A study of Mus musculus with 20 samples.

How the data were processed

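Single-cell RNA-seq of total mouse mammary epithelium was compared between a control genotype (Ctrl) and a genotype with deletion of G9a (G9aKO), the histone H3 lysine 9 methyltransferase that Ehmt2 encodes. The 20 samples of the series were the 5 sequencing runs, on 2 flow cells, of each of 4 libraries, 2 per genotype. The runs of a library shared 1 table of cells and were counted as 1 replicate. All 4 libraries were sequenced on the same 5 runs. The labels number the libraries within each genotype and do not say whether they came from separate animals. The p-values of single genes and of shares thus measure only the spread between these samples, which may be technical. The age of the mice, their stage of the oestrous cycle and the deleted part of Ehmt2 are not given in the sources used here.

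The deposited values were raw UMI counts per gene and cell barcode, without normalization. Cells were captured with a 10x Genomics 3′ kit at a target recovery of 5000 cells per library, per the labels' protocols. Cell Ranger 2.2.0, Seurat 3.0.1 and R 3.5.2 with the mm10 genome are named, per the submitters' processing notes, which give neither their roles nor their order. In each deposited table of counts, no gene was present in fewer than 5 barcodes. No barcode had fewer than 99 detected genes. The tables together listed 15617 gene symbols, of which 13174 were in all 4 tables and held 99.892% of the UMIs. A gene missing from a table was taken as 0. Of the symbols, 15106 (96.7%) match a gene of the GENCODE annotation of GRCm38, the assembly that mm10 names. Positions are taken from that annotation. Reads of endogenous retroviral loci are not analysed here, since the tables count annotated genes.

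Cells with at least 500 detected genes and a mitochondrial share of at most 10% were kept. Scrublet, run per library through scanpy 1.11.5, marked 122 of 4024, 207 of 4761, 157 of 4033 and 250 of 5151 passing cells as doublets in Ctrl replicates 1 and 2 and G9aKO replicates 1 and 2 (3.03%, 4.35%, 3.89% and 4.85%). These were removed. Counts were scaled to 10000 per cell and log-transformed for clustering only. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering (the igraph implementation) at resolution 0.8 gave the clusters, with no integration of libraries. A cluster took the name of the class whose fixed markers were most enriched, with at least 3 markers enriched 2-fold or more. It stayed unnamed where its 10 leading genes held more markers of another class than of its own. Classes are basal-like, luminal progenitor-like, hormone-sensing-like and non-epithelial.

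UMI counts were summed per library over all kept cells and over the cells of each class. Each set of sums was tested with edgeR 4.0.16 (quasi-likelihood fit with robust dispersion, TMM factors, the default low-count filter) under R 4.3.3, as G9aKO minus Ctrl, two-sided, with Benjamini-Hochberg adjustment at 0.05. Differences of the effect between classes were tested in 1 edgeR fit of all class sums with the library as a block. The standard error of a log2 fold change is its size over the square root of the F statistic. CPM values use the TMM-scaled library sizes. Shares of cells have exact Clopper-Pearson 95% intervals and were compared with an exact two-sided permutation test of 2 against 2 libraries, whose smallest possible p is 0.33. Intervals and the floor of 3 counts cover counting error only.

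There were 24 gene lists: interferon response, nucleic acid sensing, MHC class I presentation, inflammatory chemokines and cytokines, germline genes, imprinted genes, retrovirus-derived genes, H3K9 methylation and silencing machinery, basal contractile genes, basal identity, luminal progenitor identity, hormone-sensing identity, milk and alveolar genes, S phase, G2 and M phase, p53 targets, early response and dissociation genes, unfolded protein response, cholesterol synthesis, fatty acid synthesis, collagen and basement membrane genes, Wnt pathway, Notch pathway, and epidermal and squamous keratin genes. Each list with at least 5 tested members was tested in each class fit with camera (limma 3.58.1, preset correlation 0.01) and again with an estimated correlation, adjusted over the lists of a class. With the preset correlation, a camera p compares the members of a list with the other genes under an assumed correlation. It does not measure how far a list varies between libraries, so very small values can arise with few libraries. The lists, the markers, the tests, most alternatives and the rule for named genes were fixed before the data were examined.

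Named genes were Ehmt2, then in each class the up to 8 largest changes per direction among genes with an adjusted p under 0.05, a mean of at least 20 CPM in the higher group and no overlap of the groups (up to 5 for all cells). Where fewer than 3 passed, the 3 genes with the smallest p per direction were taken and are reported as not passing. From each list called by camera the 4 members with the smallest p could be named, and 2 from each other list. Predicted gene models were left out. Genes with near-identical copies (Ccl21a, Sprr, H2, histone and Oas genes) are uncertain, since UMIs of one copy can be counted for another.

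The edgeR step was tested on simulated counts with the means, totals and spread of these libraries and 100 genes changed per fold size. A 4-fold change was called for 78% of the changed genes among 13115 for all cells, 68% among 9777 for basal-like, 80% among 10709 for luminal progenitor-like and 81% among 11412 for hormone-sensing-like cells. A 16-fold change was called for 98%, 100%, 100% and 100%. Both fold sizes were changed in the same simulated counts, so the many changed genes eased the adjusted threshold. These shares thus do not give how often fewer 4-fold changes would be called in the real fits. The square root of the common dispersion was 0.35, 0.37, 0.351 and 0.327 in the same order.

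Alternatives were RLE factors, no low-count filter, a filter of 10 CPM in 2 libraries, non-robust dispersion, a shared fit of all classes, class sums thinned to the smallest total, the replicate number as a block, DESeq2 1.42.0, each library left out in turn, doublets kept, mitochondrial limits of 5% and 20%, gene limits of 200 and 1000, Leiden resolutions of 0.4 and 1.5, each library clustered alone, and classes from a per-cell marker score. Where a genotype was left with a single library, that library was assumed to vary like those of the other genotype. Such a fit reuses the other libraries of the main fit, so a gene that keeps its direction gains no separate support. Without Ctrl replicate 2 it compares G9aKO with Ctrl replicate 1 alone. To compare cycling cells and cells with an Ehmt2 UMI across depths, each cell was thinned to 2000 UMIs and shallower cells were left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.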

Results

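To ask what loss of G9a does to the developing mammary gland, single-cell 3′ RNA-seq tables of total mammary epithelium were compared between Ctrl and G9aKO mice, with 2 libraries per genotype. The study title concerns the repression of endogenous retroviruses. Ctrl replicates 1 and 2 held 41490120 and 28443098 UMIs over 7865 and 6078 barcodes. G9aKO replicates 1 and 2 held 30503664 and 25836772 UMIs over 6018 and 6690 barcodes. After filtering, 3902 and 4554 Ctrl cells and 3876 and 4901 G9aKO cells were analysed. Their median depth was 8718 and 4136 UMIs per cell in Ctrl replicates 1 and 2 and 6032 and 3629 UMIs per cell in G9aKO replicates 1 and 2.

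The cells formed 13 clusters that held the 3 known epithelial classes of the gland. There were 4897 basal-like cells, the contractile outer layer, 7202 luminal progenitor-like cells and 4922 hormone-sensing-like cells, the luminal cells that carry steroid hormone receptors. A further 156 cells were fibroblast-like. A cluster of 56 cells with the keratinocyte genes Krt6a, Krt16 and Calm4 among its leading genes stayed unnamed. Of its cells, 32 were shallow cells of Ctrl replicate 1, with a median of 1025 UMIs. With a mitochondrial limit of 20%, a cluster with these leading genes was named keratinocyte. It held 0 and 3 cells of Ctrl and 16 and 4 cells of G9aKO replicates 1 and 2. Within each epithelial class, different clusters held most of the cells of different libraries. Ctrl replicate 1 supplied 97.9% of basal-like cluster 0, 92.8% of luminal progenitor-like cluster 2 and 99.1% of hormone-sensing-like cluster 4. G9aKO replicate 2 supplied 92.8% of basal-like cluster 8, 95.6% of luminal progenitor-like cluster 3 and 92.9% of hormone-sensing-like cluster 10. Hormone-sensing-like cluster 11 came to 95.7% from G9aKO replicate 1 and cluster 12 to 96.2% from Ctrl replicate 2. Basal-like cluster 7 and luminal progenitor-like cluster 5 were shared mainly by Ctrl replicate 2, with 68.7% and 54.5%, and G9aKO replicate 1. Luminal progenitor-like cluster 6, with Fos, Egr1 and Atf3 among its leading genes, came to 40% from Ctrl replicate 2. It held 38 cells of that library, 37 of G9aKO replicate 1 and 10 of each other library. The fibroblast-like cells were mixed, with at most 28.2% from any library. All values within a class below compare these clusters.

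The targeted gene was examined first. Ehmt2, which lies on chromosome 17 at 34898469 to 34914052 on the plus strand of GRCm38, did not differ between the genotypes in any fit. Its level over all cells was 49.4 and 31.6 CPM in Ctrl replicates 1 and 2 and 30.1 and 52 CPM in G9aKO replicates 1 and 2. The log2 fold change was 0.02 (SE 0.36) over all cells, 0.04 (SE 0.36) in basal-like, −0.52 (SE 0.30) in luminal progenitor-like and −0.26 (SE 0.53) in hormone-sensing-like cells. The edgeR adjusted p were 0.995, 0.99, 0.977 and 0.999. In luminal progenitor-like cells it was 27.7 and 22.8 CPM in Ctrl and 19.4 and 15.9 CPM in G9aKO. In hormone-sensing-like cells it was 90.8 and 42.3 CPM in Ctrl and 35.1 and 76.4 CPM in G9aKO. The direction over all cells turned without Ctrl replicate 2 (−0.26) or G9aKO replicate 2 (−0.42), that in basal-like cells without the same libraries (−0.21 and −0.07), and that in hormone-sensing-like cells without Ctrl replicate 1 (0.39) or G9aKO replicate 1 (0.20). Counts from the 3′ end that lie outside the deleted part of a gene check nothing, and the deleted part is not in the labels, so these values do not check the genotypes.

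The composition of the epithelium was compared next. Hormone-sensing-like cells made up 38.4% ± 0.93 (SD, n = 2) of the G9aKO cells and 18.3% ± 1.6 (SD, n = 2) of the Ctrl cells, a ratio of 2.09. Basal-like cells made up 19.2% ± 0.74 of the G9aKO cells and 38% ± 0.27 of the Ctrl cells, a ratio of 0.504. Luminal progenitor-like cells made up 41.3% ± 1.9 and 42.2% ± 1.1, and non-epithelial cells 0.857% ± 0.029 and 0.97% ± 0.22. The 95% intervals of the hormone-sensing-like share were 16 to 18.4% and 18.3 to 20.6% in Ctrl replicates 1 and 2, and 37.5 to 40.6% and 36.4 to 39.1% in G9aKO replicates 1 and 2. Those of the basal-like share were 36.3 to 39.4% and 36.8 to 39.7% in Ctrl and 18.5 to 21% and 17.6 to 19.8% in G9aKO. The differences of 20.1 and −18.9 percentage points were larger than the spread between replicates, and each exact permutation p was 0.33, the smallest that this design allows. For the luminal progenitor-like and non-epithelial shares it was 0.667 and 1. The unnamed cluster made up 0.82% and 0.0878% of Ctrl and 0.413% and 0.0816% of G9aKO cells. Its cells of Ctrl replicate 1 were shallow, so these shares do not count keratinocyte-like cells. Classes differed in depth, with median UMIs of 12910, 9520, 9816 and 6579 in hormone-sensing-like cells and 7450, 2955, 3824 and 2872 in basal-like cells of Ctrl replicates 1 and 2 and G9aKO replicates 1 and 2, so limits on detected genes bear on these shares. At Leiden resolution 1.5 the basal-like difference was −0.0409 points, since the cluster with nearly all basal cells of Ctrl replicate 1 was led by the keratinocyte marker Krt15 and lost its name, leaving 6 basal-like cells there. The luminal progenitor-like difference of −0.895 points was −0.113 without Ctrl replicate 1, −1.68 without Ctrl replicate 2, 0.469 without G9aKO replicate 1 and −2.26 without G9aKO replicate 2.

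**Figure D1:**
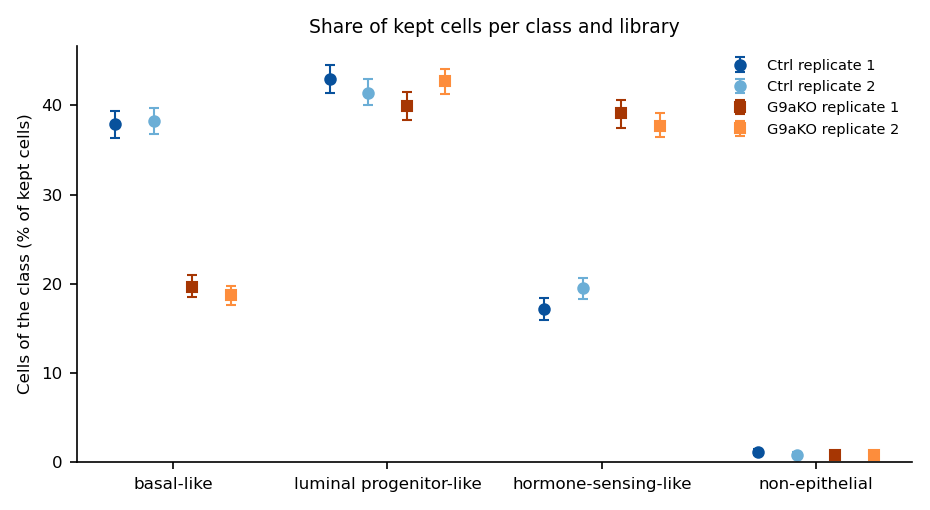
Share of kept cells (percent, vertical axis) in each class (horizontal axis) for the 4 libraries; points are libraries and bars are exact 95% intervals, which cover counting error only. The hormone-sensing-like share was 39.1% and 37.7% in G9aKO against 17.2% and 19.5% in Ctrl, and the basal-like share 19.7% and 18.7% against 37.9% and 38.2%.

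Over all cells, no gene passed the threshold, so the genes with the smallest p are given as values. The chemokine gene Ccl21a (chromosome 4, 42772860 to 42773993) was at 10.5 and 10.2 CPM in G9aKO and is not listed in either Ctrl table. Since no table lists a gene seen in fewer than 5 barcodes, no fold is given for this or other genes that the tables of a genotype do not list. Sprr1a, a cornified envelope gene (chromosome 3, 92483952 to 92485895), was at 3.91 and 6.91 CPM in Ctrl and 65.4 and 79.7 CPM in G9aKO (log2 fold change 3.75, SE 0.35). Fam25c (chromosome 14, 34351881 to 34355433) was at 60.6 and 81.4 CPM in Ctrl and 435 and 447 CPM in G9aKO (2.63, SE 0.26). Among lower genes, Gas1 was at 40.9 and 37.9 CPM in Ctrl and 7.36 and 4.96 CPM in G9aKO (−2.67, SE 0.26). Mir143hg, a microRNA host gene of smooth muscle, had a log2 fold change of −1.85 (SE 0.22), and Sostdc1, a secreted Wnt and BMP antagonist, of −2.56 (SE 0.32). edgeR called 0 of 13386 genes, with 518 higher and 751 lower at an unadjusted p under 0.05 and a lowest adjusted p of 0.313, while DESeq2 called 122 higher and 254 lower. This comparison mixes the classes, whose shares differed, so values in a class are given below.

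In basal-like cells, genes of cell division, cholesterol and fatty acid synthesis, collagens and basement membrane, MHC class I presentation and the interferon response fell as lists, and early response and hormone-sensing identity genes rose. The G2 and M phase list fell (median log2 fold change −3.19, 11 of 11 tested members lower; camera adjusted p = 0.000171, and 0.839 with an estimated correlation). Hmgb2 was at 309 and 124 CPM in Ctrl and 69.5 and 77.7 CPM in G9aKO and the proliferation marker Mki67 at 30.5 and 2.44 against 3.01 and 2.15 CPM (log2 fold change −2.68, and 0.08 without Ctrl replicate 1). The S phase list fell (median −1.10; adjusted p = 0.0301, and 0.864 with an estimated correlation), led by Dtl (−2.65, SE 0.88) and Gins2 (−1.72, SE 0.62). This call ended with sums thinned to equal totals (median −0.53; adjusted p = 0.152). The S phase (0.805, median −0.10) and G2 and M (0.135, median −0.85) calls ended without cells carrying 3 or more cycling markers. Cells with cycling markers, counted at equal depth below, made up 8.72% of the class in Ctrl replicate 1 and 0% in each other library. The cholesterol synthesis list fell (median −0.71, 20 of 23 lower; adjusted p = 0.000166, and 0.839 with an estimated correlation). The sterol oxidase gene Msmo1 was at 158 and 85.6 CPM in Ctrl and 57.8 and 48.4 CPM in G9aKO and Nsdhl at −2.04 (SE 0.72). The fatty acid list fell (median −0.48; adjusted p = 0.0175, and 0.839 with an estimated correlation), led by Lpin1 and Scd1 at −1.89 (SE 0.63) and −1.29 (SE 0.47). The collagen and basement membrane list fell (median −0.47, 27 of 29 lower; adjusted p = 0.00011, and 0.839 with an estimated correlation), with Col16a1 at 266 and 178 against 116 and 105 CPM and Col7a1, the anchoring fibril collagen, at −1.27 (SE 0.52). The MHC class I list fell (median −0.60, 16 of 20 lower; adjusted p = 0.00259, and 0.864 with an estimated correlation), with the peptide transporter Tap1 at 24.2 and 27.6 CPM in Ctrl and 15.3 and 7.52 CPM in G9aKO. The interferon list fell (median −0.43, 22 of 29 lower; adjusted p = 0.0146, and 0.864 with an estimated correlation), with Ifit1 at 11 and 5.25 against 2.41 and 1.07 CPM, although its members summed to 3560 and 5965 against 5045 and 5107 CPM. The early response list, which holds genes induced by tissue dissociation, rose (median 0.34; adjusted p = 0.0128, and 0.864 with an estimated correlation), led by Fosb (1.24, SE 0.43), while its member Btg1 was at −0.93 (SE 0.36). The hormone-sensing identity list rose (median 0.40; adjusted p = 0.0434, and 0.839 with an estimated correlation), with the fibrinogen gene Fgg at 21.2 and 25.9 CPM in Ctrl and 33.4 and 78.8 CPM in G9aKO. Its members summed to 3591 and 2976 against 3184 and 3529 CPM, and the share of hormone-sensing-like cells in the same G9aKO libraries was 2.09 times that of Ctrl. Without cells carrying 3 or more cycling markers its median was 0.39 (adjusted p = 0.0577). The summed CPM of the G2 and M, cholesterol and fatty acid lists was lower in both G9aKO libraries than in both Ctrl libraries, and that of the other 6 lists overlapped between the genotypes. None of these 9 lists passed with an estimated correlation. No single gene passed in edgeR: 0 of 10053 genes, and 0 list members over all genes or adjusted over the list alone, with 201 higher and 243 lower at an unadjusted p under 0.05 and 1 gene called by DESeq2, the histone gene Hist1h2bc. The smallest p among higher genes belonged to Fam25c, the stress-response gene Nupr1 and Gadd45g (2.77, 2.04 and 1.62, SE 0.55, 0.41 and 0.35). Fam25c was at 2.52 and 1.5 against 15.6 and 12.5 CPM, far below its 247 and 232 against 752 and 809 CPM in hormone-sensing-like cells, values chosen after they were seen. Among lower genes it belonged to Pou2af1, at 7.73 and 6.57 CPM in Ctrl and not listed in the G9aKO tables, to Hist1h2bc (−2.43, SE 0.43) and to Sesn3 (−2.04, SE 0.38). Without Ctrl replicate 2, edgeR called 433 genes, among those named here Mki67, Hmgb2, Dtl, Msmo1, Nsdhl, Lpin1, Col7a1, Ifit1, Fosb, Fam25c, Nupr1, Gadd45g, Pou2af1, Hist1h2bc and Sesn3 in the same direction (adjusted p from 0.00138 to 0.0463). Without it the interferon (camera adjusted p = 0.941, now higher), MHC class I (0.826), hormone-sensing (0.384) and fatty acid (0.0501) calls ended. Without Ctrl replicate 1, 0 genes were called and the S phase (0.11), G2 and M (0.363) and early response (0.22) calls ended and turned. The cholesterol (0.22), fatty acid (0.11) and hormone-sensing (0.11) calls ended without turning. Without G9aKO replicate 1, 8 genes were called and the S phase (0.263) and hormone-sensing (0.597) calls ended. Without G9aKO replicate 2, 0 genes were called and those of interferon (0.818), MHC class I (0.408) and collagens (0.426) ended.

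In luminal progenitor-like cells, genes of cell division fell and interferon-stimulated genes rose as lists. The G2 and M phase list fell (median −3.83, 28 of 28 tested members lower; camera adjusted p = 3.62e-50, and 0.598 with an estimated correlation). The 18 members listed in all 4 tables had a median of −3.58. Of its spindle genes, Tacc3 was at 31.6 and 10.4 CPM in Ctrl and 2.94 and 1.39 CPM in G9aKO, Bub1b at −3.11 (SE 0.70), Ndc80 at −4.36 (SE 0.98) and Kif23 at −3.54 (SE 0.82). The S phase list fell (median −1.97, 20 of 24 lower; adjusted p = 1.13e-29, and 0.598 with an estimated correlation). Of the replicative helicase genes, Mcm2 was at 25.5 and 21.1 against 5.27 and 6.63 CPM, Mcm5 at 34.6 and 11.9 against 2.7 and 1.39 CPM and Mcm3 at −2.50 (SE 0.51). Adjusted over the list alone, 26 of the 28 G2 and M members and 17 of the 24 S phase members passed, all lower, against 0 over all genes. Cells with cycling markers made up 12.5%, 1.59%, 0.35% and 0% of the class in Ctrl replicates 1 and 2 and G9aKO replicates 1 and 2. The interferon list rose (median 0.49, 26 of 39 higher and 9 of them at an unadjusted p under 0.05; adjusted p = 1.61e-06, and 0.703 with an estimated correlation). The ubiquitin-like modifier Isg15 was at 11.9 and 11.5 CPM in Ctrl and 24.4 and 46.1 CPM in G9aKO. The transcription factor Irf7 was at 7.57 and 9.87 against 17.5 and 56 CPM, Xaf1 at 5.46 and 11.8 against 20.2 and 28.1 CPM and Usp18 at 0.979 and 0.671 against 2.33 and 4.01 CPM. No member passed over all genes or adjusted over the list alone. The H3K9 methylation and silencing list fell (median −0.21, 19 of 27 lower; adjusted p = 0.00441, and 0.703 with an estimated correlation), with 0 members passing over all genes and 2 adjusted over the list alone. Its members with the smallest p, Uhrf1 (−3.59, SE 0.69) and Hells (−3.04, SE 0.62), maintain DNA methylation during replication and are also in the S phase list, and the others were the heterochromatin reader Cbx3 (−0.95, SE 0.32) and the methyltransferase gene Suv39h1 (−1.73, SE 0.59). The hormone-sensing identity list rose (median 0.65, 17 of 19 higher; adjusted p = 1.99e-05, and 0.598 with an estimated correlation). The prolactin receptor gene Prlr was at 13.4 and 16.5 against 39.9 and 31.5 CPM and Fxyd2 at 1.75 (SE 0.52). The members summed to 12118 and 35587 against 42753 and 21299 CPM, and the share of hormone-sensing-like cells in the same G9aKO libraries was 2.09 times that of Ctrl. The early response list rose (median 0.55, 26 of 32 higher; adjusted p = 8.05e-05, and 0.703 with an estimated correlation), while the heat shock genes Hsph1 and Hspa8 in it were at −1.48 (SE 0.36) and −0.87 (SE 0.32). The cholesterol synthesis list fell (median −0.34; adjusted p = 0.0248, and 0.703 with an estimated correlation), with Fdps at −0.96 (SE 0.28), and with the replicate number as a block its median was also −0.34 (0.0814). The fatty acid list also fell (median −0.24; adjusted p = 0.0114, and 0.598 with an estimated correlation), with Lpin1 at −1.20 (SE 0.38). The summed CPM of the hormone-sensing and cholesterol lists overlapped between the genotypes, and that of the other 6 lists lay past both Ctrl libraries in both G9aKO libraries, in the direction of the call. In the last 3 lists and the hormone-sensing list no member passed over all genes or adjusted over the list alone. edgeR called 0 of 10907 genes, with 203 higher and 338 lower at an unadjusted p under 0.05, and DESeq2 called 13 higher and 59 lower. The smallest p among higher genes belonged to Rgcc (0.464 and 0.767 against 7.11 and 5.4 CPM), Fam25c (2.58, SE 0.47, with means of 1.78 and 10.9 CPM) and Akr1c18, which degrades progesterone (0.0515 and 0 against 2.33 and 1.23 CPM). Among lower genes it belonged to the retinol-binding protein gene Rbp7 (22.7 and 15.4 against 3.8 and 2.47 CPM), Mcm2 and Ska1, a kinetochore gene not listed in the G9aKO tables. Without Ctrl replicate 2, edgeR called 63 genes, among those named here Mcm5, Uhrf1, Hells, Tacc3, Ndc80, Mcm3, Ska1 and Rbp7 in the same direction (adjusted p from 0.044 to 0.049). Without it the cholesterol (camera adjusted p = 0.94) and fatty acid (0.121) calls ended. Without Ctrl replicate 1, 1 gene was called and the interferon (0.0575), H3K9 (0.0797) and early response (0.832) calls ended. Without G9aKO replicate 1 the H3K9 (0.261), hormone-sensing (0.244) and cholesterol (0.261) calls ended, and without G9aKO replicate 2 that of fatty acid genes (0.055). The S phase and G2 and M calls held without each library in turn.

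In hormone-sensing-like cells, genes of cell division and of basal cells fell as lists, and early response, MHC class I, inflammatory and epidermal genes rose as lists. The G2 and M phase list fell (median −3.24, 17 of 19 lower; camera adjusted p = 3.6e-17, and 0.436 with an estimated correlation). The 16 members listed in all 4 tables had a median of −2.73, and the call ended without cells carrying 3 or more cycling markers (median −0.27; adjusted p = 0.151). The kinesin gene Cenpe was at 11.8 and 0.954 CPM in Ctrl and 0.0609 CPM in G9aKO replicate 1, and is not listed for G9aKO replicate 2, and the spindle gene Tpx2 at 20 and 1.55 against 0.122 and 0.165 CPM. The S phase list fell (median −1.65, 26 of 27 lower; adjusted p = 2.6e-24, and 0.436 with an estimated correlation), with the ribonucleotide reductase gene Rrm1 at 29.2 and 10.4 against 5.12 and 4.95 CPM. Cells with cycling markers made up 7.74% and 0.34% of the class in Ctrl replicates 1 and 2 and 0.07% and 0% in G9aKO replicates 1 and 2. The basal identity list (median −0.94; adjusted p = 6.5e-06, and 0.436 with an estimated correlation), the basal contractile list (median −0.81; adjusted p = 5.28e-05, and 0.436 with an estimated correlation) and the collagen list (median −0.98; adjusted p = 1.01e-05, and 0.436 with an estimated correlation) fell. Krt17 was at 48.9 and 36.9 against 23.7 and 19.3 CPM, Krt5 at 6.15 and 3.46 against 1.58 and 0.907 CPM, Acta2, the smooth muscle actin, at 36.6 and 15 against 12.1 and 7.91 CPM and Sparc at 10.5 and 4.05 against 1.95 and 2.8 CPM. The contractile members summed to 240 and 242 against 273 and 246 CPM, higher in G9aKO, and the basal identity members to 280 and 325 against 296 and 242 CPM. The share of basal-like cells in the same G9aKO libraries was 0.504 times that of Ctrl. The early response list rose (median 0.67, 28 of 32 higher; adjusted p = 4e-09, and 0.436 with an estimated correlation), led by Ier5 (0.94, SE 0.29) and Klf4 (0.95, SE 0.30). The MHC class I list (median 0.30, 16 of 20 higher; adjusted p = 0.000618, and 0.436 with an estimated correlation) and the inflammatory list (median 0.31, 14 of 20 higher; adjusted p = 0.0105, and 0.436 with an estimated correlation) rose. The immunoproteasome gene Psmb10 was at 35.5 and 35.4 against 47 and 85.7 CPM and the cytokine gene Il33 was at 2.09 and 6.44 against 20.8 and 13.8 CPM. The epidermal and squamous keratin list rose (median 0.23; adjusted p = 0.00321, and 0.436 with an estimated correlation). Of its members, Sprr1a was at 13.5 and 16.1 against 105 and 143 CPM, Krt13 at 1.1 and 1.32 CPM in G9aKO and not listed in the Ctrl tables, and Krt15 at −0.99 (SE 0.27). The H3K9 methylation and silencing list fell (median −0.27, 23 of 28 lower; adjusted p = 0.00108, and 0.56 with an estimated correlation), again led by Hells (−3.21, SE 0.82) and Uhrf1 (−2.67, SE 0.76). The unfolded protein response also fell (median −0.34; adjusted p = 0.00176, and 0.483 with an estimated correlation), led by Manf (−0.87, SE 0.35), as did milk and alveolar genes (median −0.28; adjusted p = 0.00934, and 0.436 with an estimated correlation), led by Abcg2 (−1.22, SE 0.40), and fatty acid synthesis (median −0.26; adjusted p = 0.00934, and 0.507 with an estimated correlation), led by the desaturase gene Fads1 (−2.10, SE 0.42). The summed CPM of the S phase, collagen, early response, epidermal and H3K9 lists lay past both Ctrl libraries in both G9aKO libraries, in the direction of the call. That of the G2 and M (904 and 226 against 214 and 304 CPM), basal identity, MHC class I, inflammatory, unfolded protein response, milk and fatty acid lists overlapped between the genotypes. None of these 13 lists passed with an estimated correlation. Adjusted over the list alone, 2 epidermal members passed higher and 1 lower and 2 fatty acid members lower, against 0 over all genes, and 0 members of the other 11 passed by either count. edgeR called 0 of 11663 genes, with 247 higher and 231 lower at an unadjusted p under 0.05 and a lowest adjusted p of 0.176, for Sprr1a, and DESeq2 called 12 higher and 16 lower. After Sprr1a (3.07, SE 0.30), the smallest p belonged to the caveolar genes Prkcdbp (24.7 and 28.6 against 101 and 119 CPM) and Cav1 (11.4 and 14.7 against 42.3 and 67.3 CPM). Among lower genes it belonged to Acot7 (49 and 46.6 against 15.9 and 15.7 CPM), Fads1 and Mthfd2 (−1.91, SE 0.38). Without Ctrl replicate 2, edgeR called 314 genes, among those named here Tpx2, Cenpe, Hells, Uhrf1, Rrm1, Sprr1a, Il33, Mthfd2, Acot7, Prkcdbp, Acta2, Cav1, Sparc, Fads1 and Krt17 in the same direction (adjusted p from 4.28e-06 to 0.0368). Without it the inflammatory (camera adjusted p = 0.802), milk (0.853, now higher), unfolded protein response (0.875, now higher) and fatty acid (0.0906) calls ended. Without Ctrl replicate 1, 2 genes were called and the MHC class I (0.804), H3K9 (0.848), fatty acid (0.139) and epidermal (0.0827) calls ended. Without G9aKO replicate 1 the milk, unfolded protein response, fatty acid and epidermal calls ended, with medians of −0.54, −0.28, −0.10 and −0.16. The epidermal median thus turned. Without G9aKO replicate 2 the inflammatory call ended and its median turned to −0.21.

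**Figure D2:**
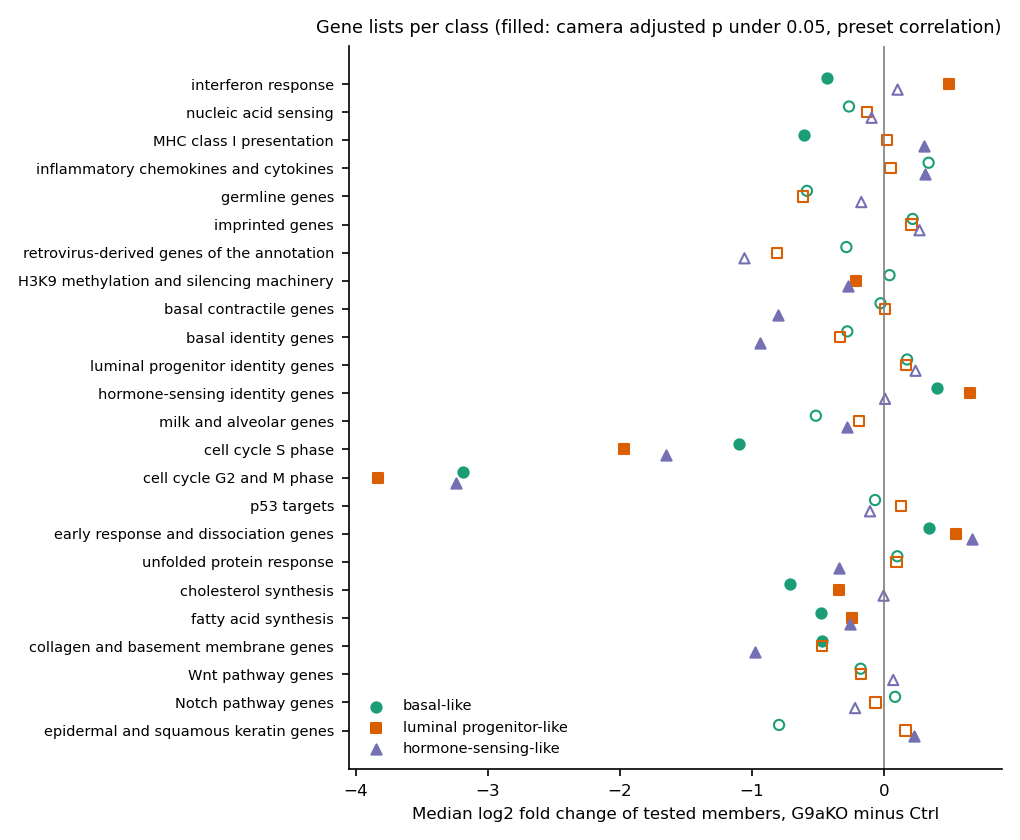
Median log2 fold change (G9aKO minus Ctrl, horizontal axis) of the tested members of each of the 24 lists (vertical axis) in the 3 epithelial classes; filled symbols have a camera adjusted p under 0.05 with the preset correlation, and none has one with an estimated correlation. The G2 and M phase list lies lowest in each class, at −3.19, −3.83 and −3.24 in basal-like, luminal progenitor-like and hormone-sensing-like cells, and the germline and retrovirus-derived lists had from 1 to 6 tested members.

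Other lists did not pass with the preset correlation. Nucleic acid sensing genes had medians of −0.27, −0.13 and −0.09 in basal-like, luminal progenitor-like and hormone-sensing-like cells (camera adjusted p = 0.785, 0.676 and 0.72), with the cell death effector Mlkl at 17.1 and 6.71 against 5.27 and 4.17 CPM in luminal progenitor-like cells. Of the 11 retrovirus-derived genes of the annotation 2 were in the tables and 1 was tested, Arc, whose log2 fold change was −0.29 (SE 0.42), −0.81 (SE 0.66) and −1.06 (SE 0.80), and in basal-like cells 0.19 without Ctrl replicate 2 and 0.04 without G9aKO replicate 2. Of the 32 germline genes, many of which are silenced by H3K9 methylation in other tissues, 7 were in the tables and 1, 4 and 6 were tested, with a median of −0.62 in luminal progenitor-like and −0.17 in hormone-sensing-like cells (adjusted p = 0.624 in the latter, where the 5 members listed in all 4 tables had −0.66). The 1 tested in basal-like cells, the homeobox gene Rhox5, was at 0 and 122 CPM in Ctrl and 80.6 and 0 CPM in G9aKO, so that the libraries of each genotype differed. Imprinted genes had medians of 0.22, 0.21 and 0.27 (adjusted p = 0.499, 0.103 and 0.191), with Phlda2 at 3.09 and 1.44 against 6.25 and 13.6 CPM in luminal progenitor-like cells. Luminal progenitor identity genes had medians of 0.17, 0.17 and 0.24 (adjusted p = 0.499, 0.171 and 0.083), p53 targets −0.07, 0.13 and −0.11 (0.963, 0.902 and 0.787), Wnt genes −0.18, −0.18 and 0.07 (0.963, 0.902 and 0.308) and Notch genes 0.08, −0.06 and −0.22 (0.834, 0.59 and 0.72). In luminal progenitor-like cells, Rspo1, a secreted Wnt amplifier, was at 76.7 and 24.4 against 10.8 and 5.4 CPM (called without Ctrl replicate 2, adjusted p = 0.0475) and Aldh1a3, a progenitor marker, at 1063 and 2322 against 3535 and 4678 CPM. Lists called in some classes did not pass in others. The interferon list had a median of 0.10 (adjusted p = 0.0625) in hormone-sensing-like cells, the MHC class I list 0.02 (0.902) in luminal progenitor-like cells and the inflammatory list 0.34 (0.142) in basal-like and 0.05 (0.0515) in luminal progenitor-like cells. In the latter, the cytokine gene Lif was at 118 and 131 against 276 and 328 CPM and 2 inflammatory members higher and 2 lower passed adjusted over the list alone, against 0 over all genes. In basal-like cells the neutrophil-directed gene Cxcl2 was at 40.4 and 141 against 340 and 2334 CPM. Csf3, also neutrophil-directed, was at 58.5 and 239 against 416 and 1713 CPM. Without G9aKO replicate 1 the log2 fold change of Cxcl2 was 4.70. Cxcl2 and Csf3 are among the leading genes of luminal progenitor-like cluster 3, which came to 95.6% from G9aKO replicate 2. RNA carried over from those cells into basal-like cells was not tested. The basal contractile list had medians of −0.03 (adjusted p = 0.927) and 0.01 (0.902) in basal-like and luminal progenitor-like cells and the basal identity list −0.28 (0.133) and −0.33 (0.0947). The H3K9 list had 0.04 (0.785) in basal-like cells, the hormone-sensing identity list 0.01 (0.0625) in its own class, and the milk list −0.52 (0.0623) and −0.19 (0.782) in basal-like and luminal progenitor-like cells. The unfolded protein response had 0.10 (0.505) and 0.10 (0.902) there, and the epidermal list −0.79 (0.0544) and 0.16 (0.0505). The cholesterol list had −0.00 (0.782) in hormone-sensing-like and the collagen list −0.47 (0.0515) in luminal progenitor-like cells. Single libraries bore on lists that did not pass. Some were called in both directions. The inflammatory list in basal-like cells was called lower without Ctrl replicate 1 (median −0.21; adjusted p = 0.0212) and higher without Ctrl replicate 2 (1.24; 5.35e-05) or G9aKO replicate 2 (0.65; 2.78e-07). The milk list in luminal progenitor-like cells was called lower without Ctrl replicate 1 (7.45e-15) or G9aKO replicate 1 (0.0362) and higher without Ctrl replicate 2 (1.31e-05). In hormone-sensing-like cells, p53 targets were called lower without Ctrl replicate 1 (0.00016) and higher without Ctrl replicate 2 (0.000267). There the cholesterol list was called lower without Ctrl replicate 1 (0.00251) or G9aKO replicate 2 (0.00359) and higher without Ctrl replicate 2 (0.0142) or G9aKO replicate 1 (0.0435). Others were called in 1 direction. Without Ctrl replicate 1 these were the milk (0.000663) and epidermal (0.00208) lists, lower in basal-like cells, MHC class I (0.00974) and basal identity (0.00894), lower in luminal progenitor-like cells, and Wnt genes (0.0275), higher in hormone-sensing-like cells. Without Ctrl replicate 2 they were higher: imprinted (0.0259) and luminal progenitor identity genes (0.013) in basal-like cells, inflammatory (0.0153), luminal progenitor identity (7.79e-05) and epidermal genes (0.00145) in luminal progenitor-like cells, and luminal progenitor identity (0.00258) in hormone-sensing-like cells. Without G9aKO replicate 1 the lower ones were milk (0.00111) and epidermal genes (0.00524) in basal-like cells and basal identity (0.0172) and collagen genes (0.0208) in luminal progenitor-like cells. The higher ones were the unfolded protein response (0.0498) in basal-like and luminal progenitor identity (0.00255) in hormone-sensing-like cells. Without G9aKO replicate 2 they were higher: imprinted genes (0.00425) in basal-like cells, inflammatory (0.000313), luminal progenitor identity (0.00854) and epidermal genes (1.39e-05) in luminal progenitor-like cells, and interferon genes (0.00275) in hormone-sensing-like cells. For some lists that did not pass, the sign of the median, the mean and the test differed. These were the H3K9, contractile and Notch lists in basal-like cells, the MHC class I, contractile, Wnt and p53 lists in luminal progenitor-like cells, and the p53 and hormone-sensing identity lists in hormone-sensing-like cells.

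The effect of the genotype was then compared between classes in a test of the difference itself. Single genes did not differ: edgeR called 0 of 12903 genes for luminal progenitor-like minus basal-like, for hormone-sensing-like minus basal-like and for hormone-sensing-like minus luminal progenitor-like cells, with 560, 855 and 350 at an unadjusted p under 0.05. No other tool was run for this test. Without Ctrl replicate 2 the counts were 55, 342 and 25, and without Ctrl replicate 1 they were 0, 0 and 1.

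Cycling cells were counted as those with at least 3 of 11 fixed proliferation markers, after each cell was thinned to 2000 UMIs. In luminal progenitor-like cells they made up 12.5% (95% interval 10.9 to 14.2%) of Ctrl replicate 1 and 1.59% (1.06 to 2.29%) of Ctrl replicate 2. In G9aKO replicate 1 they made up 0.35% (0.11 to 0.81%), and in G9aKO replicate 2 there were 0 of 1636 cells, which allows up to 0.23%. Without thinning the shares were 25.8%, 3.98%, 0.71% and 0%. In basal-like cells the thinned share was 8.72% in Ctrl replicate 1 and 0% in each other library, with upper limits of 0.25%, 0.51% and 0.47%. In hormone-sensing-like cells it was 7.74%, 0.34%, 0.07% and 0%. The table of G9aKO replicate 2 does not list 4 of the 11 markers. With the 7 listed in all 4 tables, a count chosen after the data were seen, the luminal progenitor-like shares were 7.18%, 1.14% (0.7 to 1.75%), 0.28% (0.08 to 0.71%) and 0% (up to 0.23%). Thinning left out 47, 126, 107 and 455 luminal progenitor-like cells that were shallower, in the same order of libraries. The difference between the Ctrl libraries was thus larger than that between Ctrl replicate 2 and either G9aKO library in each class.

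**Figure D3:**
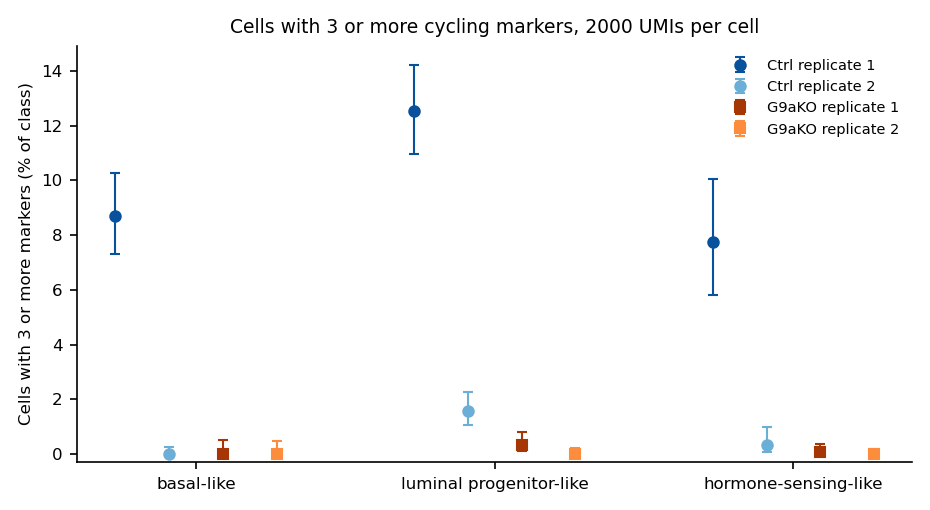
Cells with 3 or more cycling markers (percent of the class, vertical axis) at 2000 UMIs per cell, for the 3 epithelial classes (horizontal axis) and 4 libraries; points are libraries and bars exact 95% intervals for counting error. Ctrl replicate 1 lies at 8.72%, 12.5% and 7.74%, and the other libraries at 1.59% or below.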

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

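The tests of lists between classes were chosen after the results within each class were seen. With the preset correlation, the interferon and MHC class I lists were called lower in basal-like cells, the interferon list higher in luminal progenitor-like and the MHC class I list higher in hormone-sensing-like cells. With an estimated correlation none of these 4 calls passed (adjusted p = 0.864, 0.864, 0.703 and 0.436). The G9aKO effect on a list was therefore compared between classes with camera on the interaction term, for 69 pairs of list and classes, of which 18 passed. With an estimated correlation 0 of them passed (adjusted p from 0.568 to 0.98 among the 18). All values are camera adjusted p over the lists of 1 pair of classes, with the median difference in log2 fold change.

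Between luminal progenitor-like and basal-like cells, the effect on interferon genes was higher in the luminal progenitor-like cells (adjusted p = 1.06e-07, median difference 1.31, and 0.943 with an estimated correlation), as was that on MHC class I genes (0.000329, 0.78). It was lower there for the S phase list (5.59e-09, −0.96), the G2 and M phase list (0.000629, −0.49) and the H3K9 list (0.0117, −0.27). Between hormone-sensing-like and basal-like cells, it was higher in the hormone-sensing-like cells for MHC class I (4.7e-08, 1.18), interferon (0.000486, 1.02) and cholesterol synthesis genes (0.00461, 0.70). It was lower there for S phase (1.29e-05, −0.80), basal contractile (0.000109, −0.81), basal identity (0.0087, −0.47), unfolded protein response (0.0087, −0.30), H3K9 (0.0133, −0.31) and G2 and M phase genes (0.0436, −0.89). Between hormone-sensing-like and luminal progenitor-like cells, it was higher in the hormone-sensing-like cells for MHC class I genes (0.0338, 0.34) and lower for basal contractile (0.000242, −0.85), unfolded protein response (0.00659, −0.38) and hormone-sensing identity genes (0.0387, −0.43). These tests between classes were not repeated with libraries left out, but the calls within classes were. The luminal progenitor-like interferon median was 0.26 without Ctrl replicate 1 (adjusted p = 0.0575), in the same direction, and the call held without each other library. The hormone-sensing-like MHC class I call ended without Ctrl replicate 1 (median 0.15; 0.804) and held without each other library. Without Ctrl replicate 2 and G9aKO replicate 2 in turn the basal-like calls ended, with adjusted p of 0.941 and 0.818 for interferon and 0.826 and 0.408 for MHC class I genes.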

How the results depend on the processing

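The alternatives that use genes in all 4 tables, epithelial cells alone, crossed pairs, clustering without genes with an unadjusted p under 0.05 and cells without 3 or more cycling markers were chosen after seeing the data. The number of changed genes was 0 in 18 of 19 alternatives for all cells, 18 of 23 for basal-like, 20 of 24 for luminal progenitor-like and 20 of 24 for hormone-sensing-like cells. DESeq2 called 376, 1, 72 and 28 genes in the same order. With each library left out in turn the counts ran from 0 to 433 in basal-like, 0 to 63 in luminal progenitor-like and 0 to 314 in hormone-sensing-like cells. For differences between classes they ran from 0 to 55, 0 to 342 and 0 to 25. The cause was not tested. Same-numbered libraries did not deviate together (correlation −0.365, −0.342, −0.361 and −0.252). The replicate block gave 2 changed genes in basal-like cells and 0 in the others. It called the inflammatory list in 3 classes, milk genes in 2, cholesterol synthesis in 1 and epidermal genes in 3. The crossed pairing called 0, 15, 49 and 153 genes.

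For Ehmt2, thinning to equal totals gave −0.02 over all cells and −0.01 in basal-like cells, and the libraries left out in turn gave −0.42 to 0.38, −0.21 to 0.36 and, in hormone-sensing-like cells, −0.92 to 0.39. No named gene was called in the main fits. Of the 1886 alternative values of the 87 named genes, with the turned values of Ehmt2 not counted, 1810 kept direction and were not called, 70 were called and 6 turned. Those were Rhox5 in basal-like cells (0.66 with the replicate block, −11.63 to 10.88 with libraries left out), Mki67 in basal-like cells (−3.53 to 0.08) and Arc in basal-like cells (−0.71 to 0.19). Rhox5 has libraries at 0, so that its fitted values are no bound.

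The hormone-sensing-like difference kept its direction in each alternative, from 14.6 points with a marker score to 25 with at least 1000 genes. The basal-like difference, −20.8 to −15.6 points in the others, was −0.0409 points at Leiden resolution 1.5, where its fit was not run, since Ctrl replicate 1 kept 6 basal-like cells. The luminal progenitor-like difference was 0.147 with a 5% mitochondrial limit, 2.17 and −7.28 with at least 200 and 1000 genes, 1.37 with a marker score and −2.26 to 0.469 with libraries left out. The non-epithelial difference was 0.00606 and 0.0238 with 5% and 20% mitochondrial limits, 0.149 and 0.0532 with at least 200 and 1000 genes, −0.624 with each library clustered alone, −0.395 with a marker score, 0.123 with clustering without genes with an unadjusted p under 0.05 and −0.271 to 0.0444 with libraries left out. The cause was not tested. No gene was called in the main fits, so leaving out called genes would remove none. The clustering without genes with an unadjusted p under 0.05 in any class left out 1288 genes.

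With an estimated correlation the number of lists called was 0 in each class, against 9, 8 and 13, so each called list was called in 0 classes. With libraries left out, the number of classes in which a list was called ran from 0 to 1 for imprinted, p53, Wnt and unfolded protein response genes, from 0 to 2 for H3K9, hormone-sensing identity and fatty acid genes, from 0 to 3 for luminal progenitor identity, from 1 to 2 for interferon, MHC class I, inflammatory, basal identity and epidermal genes, and from 1 to 3 for milk, early response and collagen genes. Without cells carrying 3 or more cycling markers, the G2 and M phase list was called in 1 class, hormone-sensing identity in 1, luminal progenitor identity in 1, basal identity in 2 and epidermal genes in 2. Thinning to equal totals called epidermal genes in 2. Of the 30 calls, 8 held in direction without each library in turn: S phase and G2 and M phase genes in luminal progenitor-like cells and contractile, basal identity, S phase, G2 and M phase, early response and collagen genes in hormone-sensing-like cells. Depth limits low genes in basal-like cells, where 3 counts are 0.27, 0.563, 0.902 and 1.07 CPM in Ctrl replicates 1 and 2 and G9aKO replicates 1 and 2.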

Other observations

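The tests of library totals and of 6 progesterone response genes were set before their results were seen, and the other tests here were chosen afterwards. Fam25c was at 247 and 232 CPM in Ctrl and 752 and 809 CPM in G9aKO in hormone-sensing-like cells, values chosen after they were seen. Its levels in basal-like cells, 2.52 and 1.5 against 15.6 and 12.5 CPM, and in luminal progenitor-like cells, with means of 1.78 and 10.9 CPM, are so far below these that RNA carried over from hormone-sensing-like cells is not excluded there. Other genes set Ctrl replicate 1 apart in hormone-sensing-like cells, and were also chosen after their values were seen. Calca was at 5508 CPM in Ctrl replicate 1 and 94, 64.5 and 50 CPM in Ctrl replicate 2 and G9aKO replicates 1 and 2. Tnfsf11, which encodes the paracrine signal RANKL, was at 47.2, 1.91, 0.731 and 0.412 CPM and Wnt4 at 144, 35.8, 73 and 95.2 CPM in the same order.

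The hormone-sensing-like share was higher and the basal-like share lower in both G9aKO libraries. Over 4 other gene and mitochondrial limits the hormone-sensing-like difference was at least 19.6 percentage points and the basal-like difference was −16.6 points or lower. This argues against loss of cells with a mitochondrial share between 10% and 20%. It cannot decide on the gene limit, since at 200 genes a cluster of 962 shallow cells stayed unnamed, with a median of 409 UMIs. Of these, 594 and 130 came from Ctrl and 140 and 98 from G9aKO replicates 1 and 2. The limit of 500 genes left out 3477 and 1171 barcodes of Ctrl and 1717 and 1446 of G9aKO replicates 1 and 2. Class names set by clusters of single libraries are argued against for the hormone-sensing-like share by a per-cell marker score. It uses no clusters and gave a difference of 14.6 points, the lowest of 3 other ways to form the classes. Clustering each library alone or without genes with an unadjusted p under 0.05 still gave clusters of mostly 1 library, so neither tests these names. Such names do bear on the basal-like share, whose difference was −0.0409 points at Leiden resolution 1.5, where a cluster with nearly all basal-like cells of Ctrl replicate 1 lost its name. They are argued against as its whole cause, since a per-cell marker score, which uses no clusters, gave −15.6 points. That score is coarse: it put 26.2% and 26.9% of the Ctrl cells and 30.7% and 21.6% of the G9aKO cells in non-epithelial classes. Of the cells it called epithelial, 43.1% and 45.7% in Ctrl and 25% and 21.5% in G9aKO were basal-like. Unequal recovery of cell types during dissociation or capture cannot be told apart from a change in the tissue, since the non-epithelial difference of −0.113 points leaves recovery within the epithelium open. A change in composition with the genotype may underlie the shares and stays untested.

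The S phase and G2 and M phase lists were called lower in G9aKO in the 3 epithelial classes with the preset correlation and in none with an estimated correlation. Their summed CPM overlapped between the genotypes for the S phase in basal-like cells and for G2 and M in hormone-sensing-like cells. In luminal progenitor-like cells, Ctrl replicate 1 alone does not account for all of this, since the G2 and M median was −2.45 without it. That fit holds 1 Ctrl library, so variation between libraries is not excluded. Its median also takes members missing from a table as 0. UMIs per cell do not account for all of the fall either. At equal depth 1.59% of Ctrl replicate 2 cells carried 3 or more cycling markers, with an interval above those of both G9aKO libraries. With the 7 markers that the table of G9aKO replicate 2 lists, the interval of 0.7 to 1.75% lay above that library (up to 0.23%) and met that of G9aKO replicate 1 (0.08 to 0.71%), whose table lists all 11. In basal-like cells the median was 0.27 without Ctrl replicate 1, so the fall there may come from that library alone. In hormone-sensing-like cells the G2 and M median was −3.24 with all libraries and −0.97 without Ctrl replicate 1. The S phase median there was −1.65 and −0.65, so much of that fall came from the same library. The luminal progenitor-like G2 and M members summed to 1424 and 445 CPM in Ctrl and 243 and 255 CPM in G9aKO, so the Ctrl libraries differed most. A lower share of dividing luminal progenitor-like cells in G9aKO is a hypothesis, found and tested on the same 4 libraries. Variation between libraries and the stage and age of the mice stay open in it.

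Ctrl replicate 1 lay apart from the other libraries, with a mean root-mean-square log2 difference of 0.883 to them at equal totals, and G9aKO replicate 2 lay nearly as far, with 0.84. Ctrl replicate 2 and G9aKO replicate 1 had means of 0.748 and 0.71 and formed the 1 close pair, with 0.51 between them. The distance of Ctrl replicate 1 was 0.93 with totals as they are and 0.883 at equal totals, so it changed little with library totals. The planned ratio of this distance to that of the close pair was 1.73 at equal totals. It cannot decide on library totals, since the pair is the closest. The ratio was also 1.47, 1.39 and 1.65 for Ctrl replicate 2 and G9aKO replicates 1 and 2. For the same reason the distances in each class, at least 0.804 for Ctrl replicate 1 and at most 0.586 for the pair, do not decide on it. The 5 sequencing runs shared by all 4 libraries argue against the run. A progesterone-high stage of the oestrous cycle predicted that at least 5 of 6 genes would be highest in Ctrl replicate 1, and 1 was, Adamts18. Its values in basal-like cells of Ctrl replicates 1 and 2 were 18 and 17.3 CPM, and those of Axin2 were 1.86 in both. Cxcr4 was at 7.01 and 7.09 CPM in luminal progenitor-like cells, so these ranks are near ties. In hormone-sensing-like cells Cxcl12 was low (0.878 and 3.58 CPM). Ccnd1 there (74.2 and 179 CPM) and Elf5 in luminal progenitor-like cells (116 and 315 CPM) were well below Ctrl replicate 2. The count fell where the prediction had placed the outcome against this stage. The near ties and the low Cxcl12 weaken it, so it does not settle the stage. Calca, Tnfsf11 and Wnt4 are known progesterone responders, but were chosen after their values were seen. Library preparation, age and other differences between mice may be the source and were not tested. Splitting the libraries as Ctrl replicate 1 and G9aKO replicate 2 against the others called 1, 8, 22 and 22 genes in all, basal-like, luminal progenitor-like and hormone-sensing-like cells, against 0 in each for the genotypes. At an unadjusted p under 0.05 the counts were 655, 873, 950 and 656 for this split and 1269, 444, 541 and 478 for the genotypes, so within the classes they point to a structure of the samples and over all cells they run the other way. Ctrl replicate 1 and G9aKO replicate 1 against the others called 0 genes in each, with 115, 153, 81 and 550 at that p. The 3 splits are too few for a share under 0.05.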
